A study of Mus musculus with 2 samples.

How the data were processed

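Long-read RNA sequencing was measured in 2 libraries of gastrocnemius from 2 female B6CASTF1/J mice, 1 library per animal. The 2 mice are taken from the animal numbers in the labels, although the labels give both libraries the same donor identifier. As deposited, the transcript tables give raw counts, the number of long reads assigned to each transcript model, with no normalization. Per the deposited notes, reads were placed on mouse build mm10 with the GENCODE M21 annotation. The source name in the deposited transcript annotation is TALON, which assigns long reads to annotated or unannotated models. The aligner, its version, the read filters and the sequencing platform are not given in the sources used here. The deposited exon coordinates and the model lengths are in bases, and each annotation was made from the filtered alignments of its own library. The genome sequence was not used here, so splice motifs and priming within A-rich stretches were not analysed here.

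Models were joined between the libraries by transcript identifier where annotated and by gene and intron chain where not, with unannotated single-exon models pooled per gene. Single-exon models outside annotated genes were not joined, except as loci by position. The intron chain key was chosen after results had been seen, because a key that also held the class split 1 structure over 2 classes. Counts were summed per gene and divided by the library total to give counts per megaread (CPM). Library totals were 1349298 and 1359923 reads. Shares carry a 95% Wilson interval, and a fold carries the Wilson interval of the read split converted to a ratio of CPM. A count of 0 was set to a floor of 3 counts per library for folds.

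Each gene with at least 10 reads summed was tested by a two-sided Fisher's exact test of its reads against all other reads, with Benjamini-Hochberg adjustment and a threshold of 0.05. The dominant transcript of each gene with at least 20 reads in each library was tested in the same way against the gene's other transcripts. Heavy chain shares and paralogue pairs were tested by Fisher's exact test with adjustment over their own family. With 2 animals, a two-sided sign test over animals cannot give a p below 0.5, so no test between animals was made. The median log2 ratio (CPM + 1) of each of the 25 gene lists was placed among 10000 random lists of the same size, drawn from 20 expression bins with a fixed seed. A list with under 3 members carrying a read was not tested. An internal exon counted as included in a model that holds it and skipped in one that spans it. Exons with at least 20 informative reads per library and a pooled inclusion of 5% to 95% were called alternative. Exon tests were adjusted over the 170 alternative exons.

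The lists, the alternatives, the rule for named genes and the tests were fixed before the data were examined, with these exceptions. The Fisher's exact tests of the paralogue pairs and of the exons, the tests of more slow muscle, of a lower share of muscle and of the Atp2a1 reading frame, and 6 alternatives were added later. The tests of transcript length, of GC content, of fat and nerve carried along and of very short exons are exceptions too. They were made for patterns already seen in these data. The rule named the 25 genes with the highest mean CPM, up to 4 most abundant and up to 4 most changed members of each list, every heavy chain and every pair. It also named the 10 largest and 10 smallest log2 ratios among called genes with at least 20 reads in the higher library, and the panel genes, the 20 with the most reads in full. Last, it named the 10 most abundant unannotated spliced transcripts with at least 10 reads in each library, the 10 largest differences in dominant share and the 5 most abundant loci outside genes with at least 5 reads in each library. The lists were heavy chains, fast and slow fibre genes, developing fibre genes, filament and Z-disc genes, excitation-contraction coupling, glycolysis, nuclear oxidative phosphorylation, fatty acid use, the mitochondrial genome and cytosolic ribosome. The others were adipocyte, red blood cell, endothelial, smooth muscle, fibroblast, tendon, macrophage, nerve and Schwann cell and satellite cell markers, neuromuscular junction, early response, circadian, fasting and imprinted genes.

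The gene test was tested on simulated data with known changes. The changed genes were drawn from those with at least 20 reads summed. Of 100 genes changed 2-fold, 47% were recovered, and 82.6% of those with at least 100 reads. Of 100 changed 4-fold, 84% were recovered. Of 9121 unchanged genes, 6 were called, and with no change at all 0 of 9308 were called. With a dispersion of 0.01 between animals and no change, 190 of 9295 were called. In the dominant transcript test, 98% of 200 shares moved by 25 points were recovered, and 8 of 1324 unchanged genes were called. That simulation held only the 1524 genes with at least 200 reads summed, so recovery among the genes with fewer reads was not measured. A list moved 2-fold gave a median log2 ratio of 1.01, and 0 of 23 unchanged lists stood apart. The list simulation held counting noise alone, so it does not measure how often lists stand apart through spread between animals.

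The alternatives were TMM factors from edgeR 4.0.16, size factors from DESeq2 1.42.0, other read minimums and pseudocounts, totals without mitochondrial and spike-in reads, annotated transcripts alone, a chi-square test, edgeR's exactTest with a dispersion of 0.01, division by transcript length and leaving out each library. The 6 added after the data were seen were spliced models alone, M21 exons alone, classes without Atp2a1, the key with class, exon limits on the mean of both libraries, and no exon limits. The trends with transcript length and GC content were refitted on genes with at least 10 reads after an earlier fit had left a trend, with the same outcome. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.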

Results

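Long-read RNA sequencing was done on the gastrocnemius, the large calf muscle, of 2 female mice aged 2 months. The strain, B6CASTF1/J, is a hybrid of the B6 and Cast strains. The labels define 1 group: replicate 1 came from animal 3 and replicate 2 from animal 4, each with 2 µg of starting RNA. They also give both libraries the same donor identifier, which was not resolved, so the count of 2 animals rests on the animal numbers. The deposited tables held 1349298 reads for replicate 1 and 1359923 reads for replicate 2, as counts of reads per transcript model. A transcript model is one exon structure to which reads were assigned. Replicate 1 had 85714 models and replicate 2 had 92049, of which 60.4% and 60.1% rested on a single read. With 1 group, no comparison between groups was possible. The values below describe the muscle and how far the 2 animals' libraries differed, as mean ± SD with n = 2 or per library. Every test on reads compares these 2 libraries and not animals as a population, and none of the differences has a replicate check. Intervals, floors and p-values cover counting error only.

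Reads came from 13844 annotated genes in replicate 1 and 13792 in replicate 2. Both libraries held 12265 of the 15371 genes seen in either, or 79.8%. Genes seen in a single library were scarce there, with a median of 1 read. At a minimum of 10 reads in each library, 6864 genes remained. Across the 15371 genes, log2(CPM + 1) in the 2 libraries had a Pearson correlation of 0.942 and a Spearman correlation of 0.920. Genes are not independent replicates, so these values carry no p. Over 7470 genes with at least 20 reads summed, chi-square divided by its degrees of freedom was 5.90, so the files do not hold 1 library under both labels. The value was used for nothing else, since it sets the difference between animals against counting noise alone.

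Genes of contraction and of rapid energy supply headed the list of abundant genes. Atp2a1, which encodes the calcium pump of fast fibres and lies at 7:126444130-126463108 (mm10), held 201493 reads in replicate 1 and 194599 in replicate 2. That was 14.9% and 14.3% of all reads (14.6% ± 0.441, SD, n = 2). Acta1, the skeletal muscle actin, followed with 74992 and 68399 reads, and Ckm, the muscle creatine kinase, with 60801 and 66599. Tnnc2, the fast troponin C, had 22353 and 25746 reads. Tpm1, a tropomyosin, had 18006 and 15296, and Aldoa, an enzyme of glycolysis, 17899 and 12416. The 10 genes with the most reads took 32.9% and 31.9% of each library. The other genes among the 25 with the highest mean CPM were Myh4, Slc25a4, Eno3, Actn3, Ldha, Myh1, Mylpf, Myl1, Car3, Gsn, Ak1, Tcap, Mybpc2, Pkm, Tpm2, Casq1, Atp5b, Pfkm and Des. Ldha and Atp5b were the 2 of these 25 that did not differ between the libraries by Fisher's exact test. The folds of replicate 2 over replicate 1 ran from 0.629 for Gsn to 1.27 for Myh4. None of the 25 was called by edgeR's exact test with a dispersion of 0.01, which assumes a biological coefficient of variation of 10%. The log2 ratio of Aldoa was -0.54 over all its transcripts and 0.31 when annotated transcripts alone were counted, so its direction depends on that choice.

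Gene by gene, 9341 genes had at least 10 reads summed over both libraries, and 730 of them (7.82%) differed at a Benjamini-Hochberg adjusted p under 0.05 by Fisher's exact test. Of these, 397 were higher in replicate 2 and 333 were lower, and 301 differed by more than 2-fold. The median log2 ratio over all tested genes was -0.01. The balance turned to 336 higher and 370 lower without mitochondrial and spike-in reads, to 231 and 279 with annotated transcripts alone, and to 303 and 320 with spliced models alone, a choice made after the data were seen. With a dispersion of 0.01 between animals in edgeR's exact test, 173 genes differed, 83 higher and 90 lower in replicate 2.

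The myosin heavy chains, the motor proteins that define fibre types, were mostly those of fast fibres in both animals. Myh4, the type IIb chain, held 52.0% (95% Wilson interval 51.4 to 52.7) and 48.3% (47.8 to 48.8) of the sarcomeric heavy chain reads, a mean of 50.2% ± 2.65 (SD, n = 2). Myh1, the IIx chain, held 8519 of 24416 reads in replicate 1 and 10134 of 33781 in replicate 2 (32.4% ± 3.46). Myh2, the IIa chain, held 11.2% and 8.48% (9.86% ± 1.94). Myh7, the chain of slow fibres, at 14:54970684-54994543, held 422 of 24416 reads in replicate 1, or 1.73% (1.57 to 1.90). In replicate 2 it held 4414 of 33781, or 13.1% (12.7 to 13.4). Its mean of 7.40% ± 8.02 (SD, n = 2) therefore rested on 2 animals far apart. In counts per library total, Myh7 (ENSMUSG00000053093.16) was 10.4-fold higher in replicate 2 (9.39 to 11.5). Myh7b, a slow-type chain with an intronic microRNA, had 1 and 18 reads, a ratio of 17.9 (3.03 to 105). The developmental chain Myh3 had 6 and 16 reads, the cardiac chain Myh6 had 12 and 13, and the perinatal chain Myh8 had 5 and 3. Myh13, of eye and throat muscles, had 1 read in replicate 1 and 0 of 33781 in replicate 2, which allows a share of up to 0.00888%. When annotated transcripts alone were counted, the mean share of Myh4 was 21.7% and that of Myh1 54.1%. Myh7 then held 3.31% and 23.3%, which in replicate 2 was above the 22.8% of Myh4. Annotated transcripts held 15.4% and 21.3% of Myh4 reads, incomplete splice matches 45.5% and 47.0%, and transcripts with an unannotated splice site 38.1% and 30.5%.

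The fast gene held most reads of all 9 pairs of fast and slow paralogues, except for troponin T in replicate 2. The fast share of the pair Tnnt3 and Tnnt1, the tropomyosin-binding troponins, was 84.5% (82.8 to 86.0) in replicate 1 and 44.0% (42.6 to 45.5) in replicate 2. For the inhibitory troponins Tnni2 and Tnni1 it was 98.3% and 87.8%, and for the calcium-binding Tnnc2 and Tnnc1 99.1% and 95.0%. The calcium pumps Atp2a1 and Atp2a2 gave 99.9% and 99.4%, the regulatory light chains Mylpf and Myl2 98.6% and 96.2%, and the calcium stores Casq1 and Casq2 98.7% and 97.0%. The Z-disc pairs gave 91.0% and 88.4% for Myoz1 and Myoz2 and 72.9% and 69.4% for Actn3 and Actn2. Mybpc2 and Mybpc1, the myosin-binding proteins C, were the only pair with a higher fast share in replicate 2, with 59.9% and 62.9%, but this did not hold when annotated transcripts alone were counted (82.0% and 82.0%). With that choice the pairs Tnnt3 and Tnnt1 and Tnni2 and Tnni1 stood at 100% in both libraries. The reason is that no read of Tnnt1 or Tnni1 lay on an annotated transcript. The calcium pumps then stood at 0% in both, since no read of Atp2a1 did. These values are fixed by the choice itself, so they cannot decide on the exception for troponin T or on the differences between the libraries. A 14-base coding exon of Tnnt1 that every annotated coding transcript over it holds was included in 0% of 55 and 166 informative reads. For a 4-base exon of Tnni1 this was 0% of 67 and 327. All 9 pairs differed between the libraries by Fisher's exact test, the highest adjusted p being 6.07e-04 for Myoz1 and Myoz2.

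**Figure D1:**
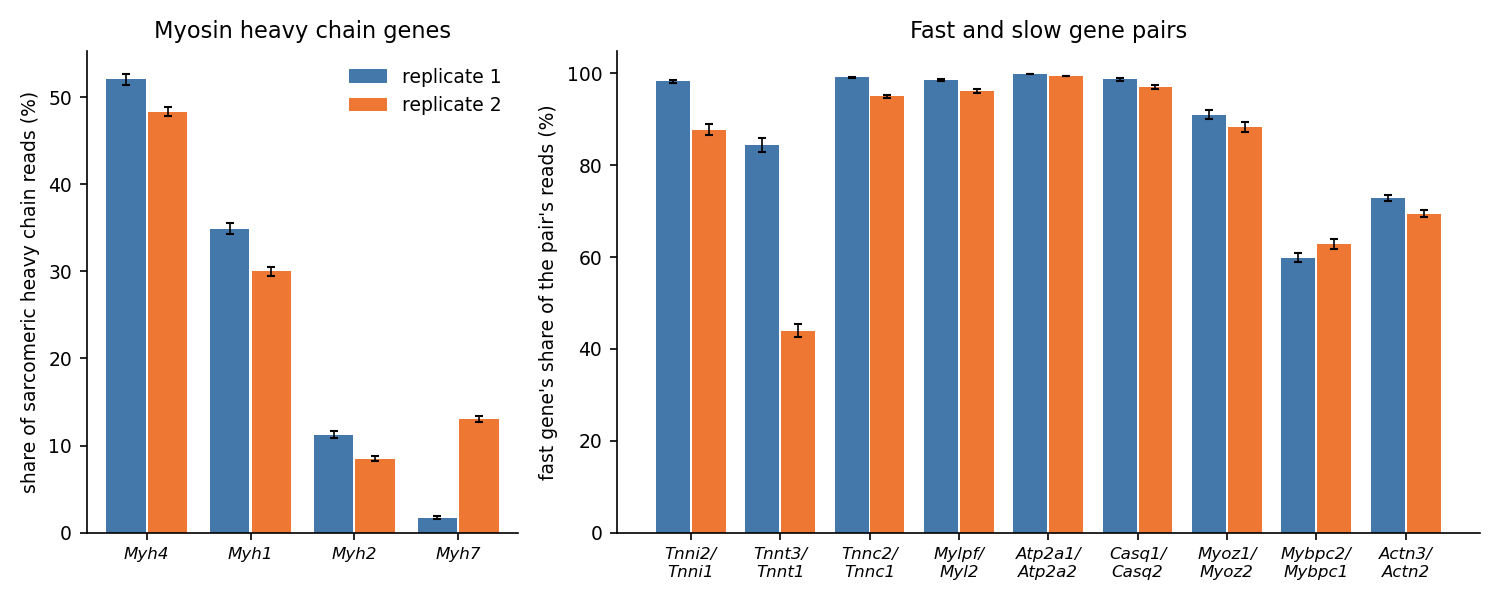
Left, share of sarcomeric myosin heavy chain reads per gene (%), and right, share of each pair's reads held by the fast gene (%), per replicate with 95% Wilson intervals. Myh7 stands at 1.73% in replicate 1 and 13.1% in replicate 2, and the troponin T pair is the only one below 50% in either library.

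The slow fibre list as a whole stood apart. Of its 13 genes, 10 were higher and 2 lower in replicate 2, with the same counts when adjusted over the list alone. Its median log2 ratio was 2.28, against a central 95% range of -0.16 to 0.25 in 10000 random lists matched on expression. It was 1.44 over the 10 genes with a read when annotated transcripts alone were counted and 1.68 with a pseudocount of 10 CPM, still above the random ranges. After Myh7b, with 1 and 18 reads, and Myh7, the steepest by fold were Tnnt1 with 307 and 2599 reads (8.40-fold, 7.46 to 9.45), Tnnc1 with 202 and 1354 (6.65-fold, 5.74 to 7.71), the slow tropomyosin Tpm3 with 267 and 1615 (fold interval 5.27 to 6.83) and Atp2a2 with 191 and 1082 (5.62-fold, 4.82 to 6.55). The exceptions were Mb, the oxygen store myoglobin (1514 and 1099 reads), and the alpha-actinin Actn2 (4051 and 3756), both lower in replicate 2. The fast fibre list was lower in replicate 2 by a small amount, with a median log2 ratio of -0.11, just past its random range of -0.11 to 0.23. Of its 16 genes, 5 were higher and 9 lower (10 lower when adjusted over the list alone). Tnni2 had 3945 and 2490 reads, though its log2 ratio of -0.67 became 0.06 when annotated transcripts alone were counted. Actn3 (10905 and 8538 reads) and Myoz1 (3168 and 2517) were also lower in replicate 2. The fast list no longer stood apart when annotated transcripts alone were counted.

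**Figure D2:**
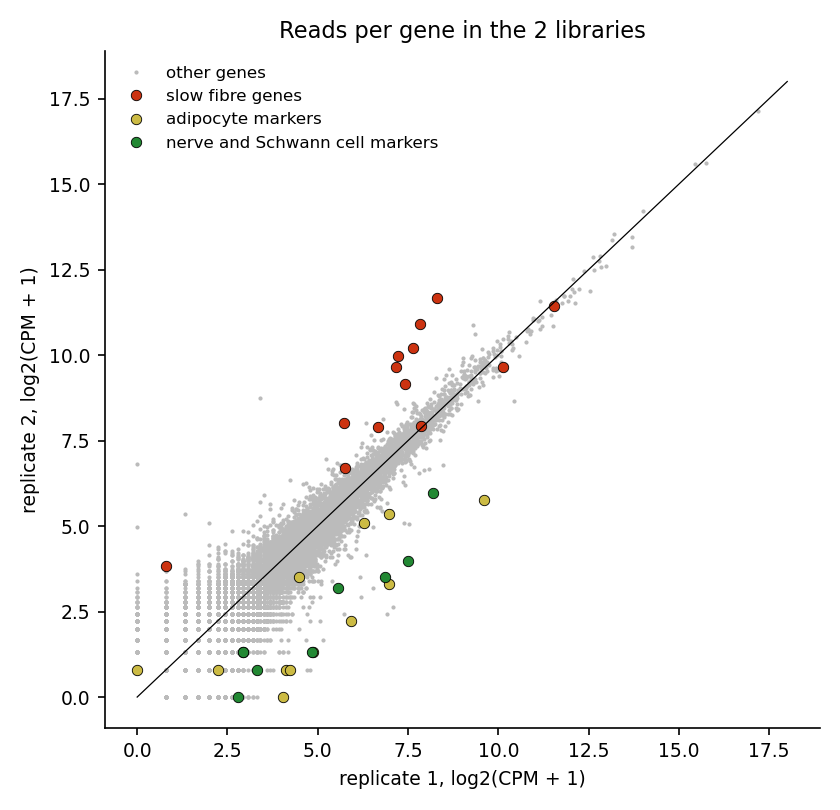
Each point is a gene, with log2(CPM + 1) in replicate 1 on the horizontal axis and in replicate 2 on the vertical axis, and the line marks equality. The slow fibre genes lie mostly above the line, and the nerve and Schwann cell markers and all but 1 of the adipocyte markers lie below it.

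The adipocyte and the nerve and Schwann cell lists had the lowest medians of the 25 lists. Adipocyte markers had a median log2 ratio of -3.38 (random range -0.39 to 0.31), or -3.82 with genes at 0 in one library set to a floor of 3 counts. It was -1.36 with a pseudocount of 10 CPM and -3.83 with 0.1, both below the random ranges. Of the 10 markers tested, 9 were lower and 0 higher, and 10 were lower when adjusted over the list alone. Cfd, the protease adipsin, had 1058 reads in replicate 1 and 73 in replicate 2, a 14.6-fold difference (11.5 to 18.5). The fat-droplet gene Cidec had 168 and 12, the hormone genes Adipoq 80 and 5 and Retn 21 and 0, Fabp4 169 and 54, and Thrsp 103 and 45. Retn was at least 7.06-fold higher in replicate 1. Nerve and Schwann cell markers had a median of -2.51 (-0.47 to 0.41), which was -1.63 with a pseudocount of 10 CPM and -3.43 with 0.1, again below the random ranges. Of 8 tested, 6 were lower and 0 higher, and 8 were lower when adjusted over the list alone. The myelin genes led them, with Pmp22 at 395 and 84 reads, Mbp at 245 and 20, Cnp at 62 and 11, Prx at 37 and 2 (18.6-fold, 4.96 to 70.1) and Mal at 12 and 1. Neuromuscular junction genes had a median of -0.61 (-0.45 to 0.37), but 0 of 9 tested passed, and 1 was lower when adjusted over the list alone; Rapsn had 58 and 70 reads, Ache 46 and 23, Chrna1 37 and 19, and Chrnb1 28 and 18. Endothelial markers had a median of -0.34, just past a range of -0.33 to 0.30, with Cav1 (151 and 96 reads) the only one of 12 called and 3 lower when adjusted over the list alone. Tendon markers went the other way, with a median of 0.59 (-0.40 to 0.42). Of 6 tested, 2 were higher, the same when adjusted over the list alone: the collagen-binding Fmod (223 and 470 reads) and Chad (40 and 77). The endothelial and tendon lists no longer stood apart with a pseudocount of 10 CPM.

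Thick and thin filament and Z-disc genes had a median log2 ratio of -0.13 (-0.08 to 0.18), with 7 of 36 higher and 14 lower (8 and 15 when adjusted over the list alone). Within that list Tpm3 and the myosin-binding Mybph (24 and 109 reads) were higher in replicate 2, while the muscle LIM protein Csrp3 (481 and 150) and the tropomyosin Tpm2 (6069 and 4035) were lower. Mitochondrial genome genes had a median of 0.43 (-0.26 to 0.24), with 6 of 11 tested higher and 0 lower (8 when adjusted over the list alone). Mt-Cytb, for a subunit of complex III, had 416 and 882 reads, and mt-Co1 1064 and 1264. Nuclear oxidative phosphorylation genes had a median of 0.20 (-0.07 to 0.18), with 21 of 39 higher and 2 lower (24 and 4 when adjusted over the list alone), Ndufc1 (558 and 800 reads), Uqcrb (616 and 856) and Cox8b (757 and 1030) among the higher. All reads of mitochondrial genes made up 0.176% and 0.247% of the libraries (0.212% ± 0.0506, SD, n = 2).

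**Figure D3:**
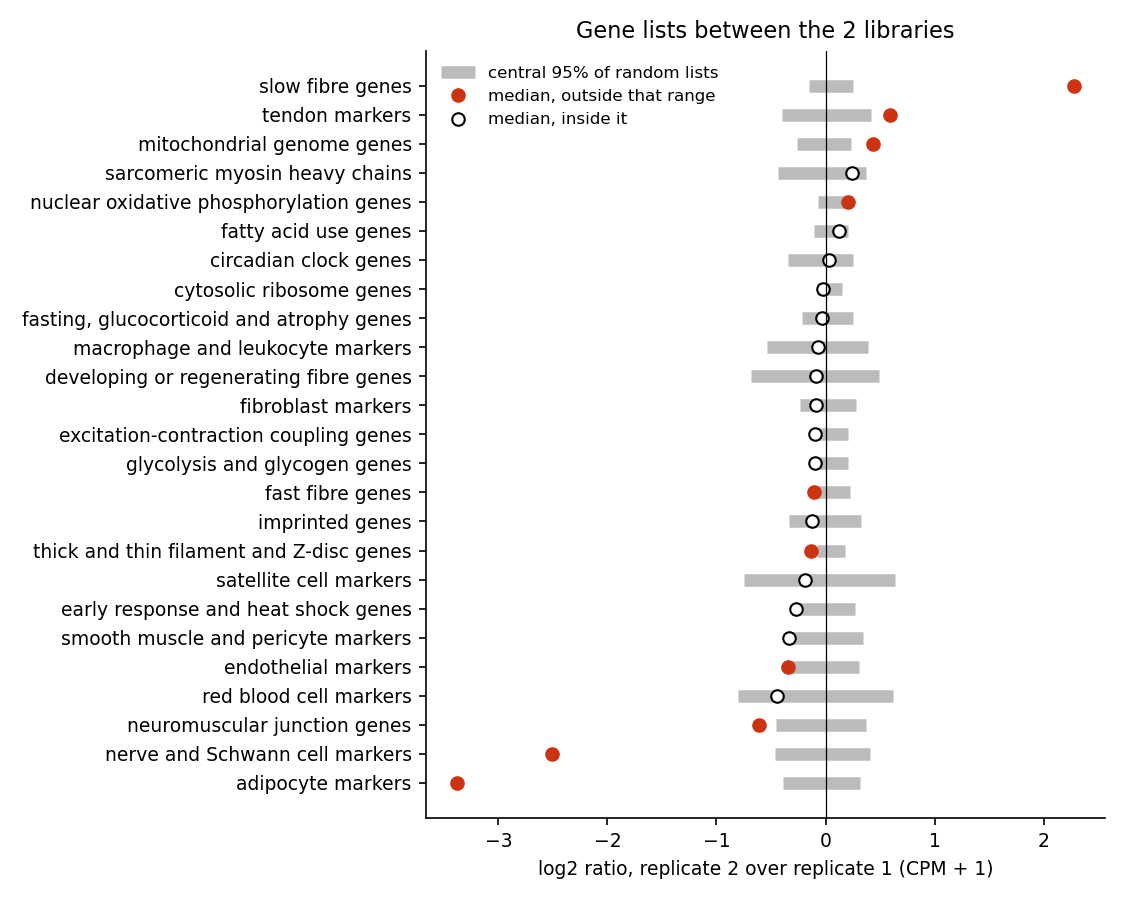
Median log2 ratio of replicate 2 over replicate 1 (CPM + 1) for each of the 25 gene lists, with the central 95% range of matched random lists as a grey bar. The medians outside that range are filled, and run from -3.38 for adipocyte markers to 2.28 for slow fibre genes.

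The other 15 lists stayed within their random ranges at the main setting, where 10 of 25 stood apart. Some lists share members, so their results are not separate findings. The fast fibre list shares Atp2a1 and Casq1 with excitation-contraction coupling, Actn3 and Myoz1 with the filament and Z-disc list, and Eno3 with glycolysis. With a pseudocount of 10 CPM 11 stood apart, among them heavy chains (0.24), smooth muscle (-0.33) and early response genes (-0.19). With at least 10 reads summed 12 of 24 did, among them developing fibre (1.09) and glycolysis genes (-0.10). With annotated transcripts alone 14 did, among them heavy chains (0.63), developing fibre (1.21), excitation-contraction coupling (-0.27), ribosome (-0.13) and smooth muscle genes (-0.62). Excitation-contraction coupling genes had a median of -0.10 (percentile 2.77 among random lists), with 6 of 23 tested higher and 5 lower, or 6 and 10 when adjusted over the list alone. The calcium-binding Hrc (843 and 2587 reads) and the junctional Trdn (704 and 1201) were higher in replicate 2. Glycolysis and glycogen genes had a median of -0.10 (percentile 2.60), with 4 of 21 higher and 8 lower, or 4 and 10 when adjusted over the list alone. Fatty acid use genes had 0.12 (81.5), with 6 of 22 higher and 0 lower, or 6 and 1 when adjusted over the list alone; the carrier Fabp3 had 876 and 2113 reads and the kinase Pdk4 704 and 1315. Myosin heavy chains had 0.24 (92.0), with 4 of 7 higher and 0 lower, the same when adjusted over the list alone. Developing or regenerating fibre genes had -0.08 (52.4), with 2 of 5 higher, Myog (36 and 79 reads) and Actc1 (9 and 38), and 2 higher and 1 lower when adjusted over the list alone; this list was higher in replicate 2 with at least 10 reads summed or with annotated transcripts alone. Cytosolic ribosome genes had -0.02 (17.9), with 1 of 48 higher and 4 lower, or 3 and 5 when adjusted over the list alone. Smooth muscle and pericyte markers had -0.33 (3.33), with 5 of 9 lower, and 5 when adjusted over the list alone, among them Cnn1 (33 and 3 reads), Myl9 (88 and 26) and Acta2 (92 and 38).

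Fibroblast markers had a median of -0.09 (percentile 18.6), with 1 of 12 higher and 2 lower, or 1 and 3 when adjusted over the list alone; Gsn was lower and Col1a2 higher. Macrophage and leukocyte markers had -0.07 (45.7), with 1 of 9 lower, Lyz2 (70 and 34 reads), or 2 when adjusted over the list alone. Red blood cell markers had -0.44 (15.2) over 4 tested genes, satellite cell markers -0.19 (32.1) over 2, and circadian clock genes 0.03 (76.8) over 11, each with 0 calls and 0 when adjusted over the list alone. Early response and heat shock genes had -0.27 (3.87), with 3 of 14 higher and 2 lower, or 3 and 3 when adjusted over the list alone; the chaperone genes Hspa1b (5 and 21 reads), Dnajb1 (20 and 61) and Hsph1 (68 and 148) were higher. Fasting, glucocorticoid and atrophy genes had -0.04 (32.1), with 3 of 16 higher and 3 lower, or 3 and 5 when adjusted over the list alone. In that list Foxo1 (27 and 60 reads) was higher, and the muscle ubiquitin ligase genes Trim63 (477 and 299) and Fbxo32 (139 and 77) were lower. Imprinted genes had -0.13 (18.3), with 2 of 12 lower, Nnat (36 and 1) and Gnas (1448 and 1212), and the same 2 lower when adjusted over the list alone. With genes at 0 in one library set to the floor, or left out where both libraries were at or under it, and no pseudocount, the median was 0.29 for heavy chains, 0.16 for developing fibre genes, 0.37 for the mitochondrial genome and -0.10 for red blood cell markers. It was then -0.30 for macrophage, 0.14 for satellite cell, -0.29 for early response, 0.09 for circadian and -0.18 for imprinted genes, so that the developing fibre and satellite cell lists changed sign. No list changed the sign of its median under the TMM or DESeq2 scaling or without mitochondrial and spike-in reads.

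Among called genes with at least 20 reads in the higher library, the 10 largest and the 10 smallest log2 ratios were taken. Higher in replicate 2, besides Myh7, Tnnt1, Tnnc1, Tpm3 and Atp2a2, were Usp50, Topbp1, Gm8424, Gm6563 and Gm34302. Usp50, a deubiquitinase-like gene, had 0 and 153 reads, at least 50.6-fold higher, and all 153 lay on 1 single-exon model at 2:126709096-126709354. That model ends where a single-exon model of Gm10774 begins on the same strand, which had 95 reads in replicate 1. Topbp1, a DNA damage response gene, had 13 and 581 reads (44.3-fold, 25.8 to 76.3), but 570 of the 581 lay on 1 single-exon model at 9:103347985-103355313. In replicate 1, 137 reads of a single-exon model within that span were assigned to a locus outside annotated genes. With spliced models alone, a choice made after the data were seen, its log2 ratio was -0.23, and with annotated transcripts alone -0.41. Gm8424 (0 and 41 reads, at least 13.6-fold) and Gm6563 (2 and 54, ratio 26.8, 7.19 to 99.7) are processed pseudogenes, which resemble their parent genes, so both are uncertain. Of the Gm8424 reads, 27 lay on 1 intron chain that in replicate 1 had 27 reads assigned to Maged2. These places were looked up after the values were seen. Gm34302 had 4 and 45 reads (11.2-fold, 4.18 to 29.8). Higher in replicate 1, besides members of the adipocyte and the nerve and Schwann cell lists, were Mup22 and Hp. Mup22, a urinary protein gene of a near-identical family and therefore uncertain, had 162 and 6 reads (27.2-fold, 12.3 to 60.2). Hp, haptoglobin, had 181 and 7 (26.1-fold, 12.5 to 54.5). Cdo1, of cysteine metabolism, had 34 and 1 reads (34.3, 5.93 to 198) and Nnat, an imprinted gene, 36 and 1 (36.3, 6.28 to 210). Whether Mup22, Hp, Cdo1 and Nnat are also expressed in fat or nerve was not tested. Among the fat genes, Pck1, of glucose and glycerol synthesis, had 38 and 2 (19.1, 5.10 to 71.9).

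Annotated transcripts held 66.1% of reads in replicate 1 and 63.5% in replicate 2 (64.8% ± 1.85, SD, n = 2). Transcripts with an unannotated splice site held 17.5% and 17.1% (17.3% ± 0.347), and without Atp2a1, a choice made after the data were seen, the mean was 3.73%. Models given as incomplete splice matches, a class for transcripts that lack exons at an end of an annotated one, held 7.63% and 8.43% (8.03% ± 0.560), and of their reads 79.8% and 80.2% were given as keeping the 3' part. New combinations of annotated splice sites held 5.31% and 4.97% (5.14% ± 0.244). Models of the class given as genomic held 1.96% and 2.69%, antisense models 1.18% and 2.93%, and intergenic models 0.221% and 0.413%. The antisense share was 2.48-fold higher in replicate 2. By number of models, annotated transcripts made up 18.1% in replicate 2 and 19.9% in replicate 1 and unannotated splice sites 20.5% ± 0.693 (SD, n = 2). Checked against M21, 5.76% and 5.55% of the reads in multi-exon incomplete splice matches had a splice site absent from M21, and 1.15% and 1.31% had annotated sites in an unannotated junction, so the description of that class does not cover them. Likewise, 68.2% and 65.6% of the reads in new combinations used annotated junctions throughout, and 15.5% and 18.5% had a splice site absent from M21.

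**Figure D4:**
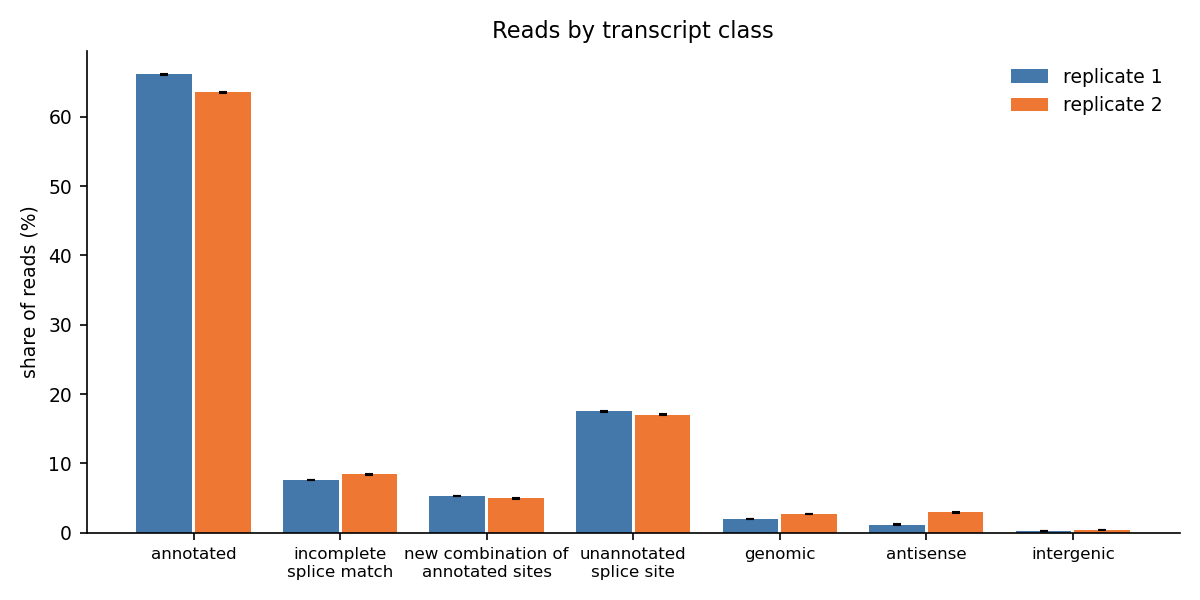
Share of reads (%) per transcript class in each replicate, with 95% Wilson intervals. Annotated transcripts hold 66.1% and 63.5%, and unannotated splice sites 17.5% and 17.1%.

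Among 7470 genes with at least 20 reads summed, the most abundant transcript was annotated in 6351 and not annotated in 1119. From replicate 2 alone that count was 773, and from replicate 1 alone 663, since fewer genes reach the minimum in 1 library. The 1119 were 390 new combinations of annotated splice sites, 322 genomic models, 269 incomplete splice matches and 138 models with an unannotated splice site. All unannotated single-exon models of a gene were pooled here as 1 transcript, under the class of the member with the most reads. In such a gene no single unannotated model need hold more reads than the annotated transcript. Spliced unannotated transcripts with at least 10 reads in each library numbered 864. The most abundant was the main Atp2a1 transcript, with 191477 reads in replicate 1 and 185860 in replicate 2, or 95.0% and 95.5% of the gene. It spanned 7:126445858-126463108 with 22 exons and lacked exon 2 of the 23 in Atp2a1-201, a coding exon of 18 bases at 7:126462500-126462517. That exon was included in 1 of 196045 and 1 of 190313 informative reads. In its place, the exon before it ran 26 bases further. A similar Atp2a1 transcript of 3480 bases had 689 and 658 reads.

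The other abundant unannotated transcripts belonged to Aldoa, Myh4, Tnni2, Srl, Ndrg2, Oaz1, Vdac3 and Idh3b. The main Aldoa transcript differed from Aldoa-201 in its intron nearest the 5' end, which began at another annotated site, and held 85.2% and 77.8% of the gene's reads. The main Myh4 transcript had an extra intron upstream, between 67237834 and 67238030 on chromosome 11, absent from M21, and held 36.6% and 29.1%. Tnni2 had one with 71.4% and 57.1% of its reads. Srl, sarcalumenin, had one with 49.6% and 51.2%, Ndrg2, a stress-responsive gene, with 41.7% and 38.1%, and Idh3b, of the citric acid cycle, with 89.8% and 89.8%. The unannotated junction of the Tnni2 transcript, from 142442499 to 142443170, spans a 7-base coding exon included in 0% of 3668 and 2166 informative reads. The loss of very short exons weighed below for Atp2a1 may therefore apply to it as well. In Oaz1, which is translated with a programmed frameshift, 95.6% and 95.7% of reads lacked an annotated intron of a few bases. In Vdac3, a mitochondrial channel, 651 of 723 and 722 of 849 reads used a splice site 1 base from an annotated one.

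Of the 72 genes chosen for their known or expected splice variants, 65 had at least 20 reads in each library, and the most abundant transcript held a median of 52.4% of a gene's reads. It was annotated in 41 genes, a new combination of sites in 12, an incomplete splice match in 10 and held an unannotated splice site in 2. Among the 20 panel genes with the most reads, Atp2a1 (95.3% ± 0.339) was joined at the top by Car3 (97.3% ± 0.208), Tpm1 (96.1% ± 0.609), Pkm (91.2% ± 0.129), Atp5c1 (90.9% ± 0.852) and Tpm2 (89.3% ± 0.493; SD, n = 2). Des, the intermediate filament desmin, had 86.1% ± 12.3, Tnnt1 86.4% ± 7.88, Tpm3 85.9% ± 7.03, Fhl1 84.6% ± 1.99, Slc25a3 83.9% ± 0.0563 and Mybpc2 82.9% ± 1.73. Intermediate shares were seen in Cacna1s (66.1% ± 3.55), Myl1 (64.5% ± 0.458), Bin1 (58.7% ± 1.03) and Myom1 (52.4% ± 6.10). Lower shares were seen in Trdn (31.9% ± 24.6), Ryr1 (29.7% ± 2.52), Mybpc1 (28.7% ± 3.14) and Tnnt3, where 238 transcripts carried reads and the main one held 10.3% ± 1.17. Those of Ryr1, Trdn and Tnnt1 were incomplete splice matches. A coding exon of 14 bases in Tnnt3, of 14 in Tnnt1 and of 18 in Ryr1 was included in 0% of informative reads in both libraries. One of 18 bases in Trdn was included in 100% and 99.4%. The transcript shares of Tnnt3, Tnnt1 and Ryr1 are therefore uncertain. In Pkm, the exon at position 9 of Pkm-201, counted within that transcript, was included in 1.22% (0.972 to 1.54) and 0.903% (0.676 to 1.21) of reads. Both values lie under the 5% from which an exon was called alternative. The inclusion of the muscle exon itself is not given here.

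Across genes with at least 20 reads in each library, 83 of 4881 dominant transcripts differed in share by Fisher's exact test, 36 with a higher and 47 with a lower share in replicate 2. The 10 with the largest difference were Lrg1, Pnisr, Exosc9, Tmem232, Coq3, Cep83, Rpl39, Acot13, Maged2 and Dpm1. Lrg1-201 of Lrg1, a secreted glycoprotein gene, held 171 of 246 reads in replicate 1 and 3 of 44 in replicate 2. For Tmem232, the dominant transcript was the pool of its unannotated single-exon models, with 4 of 26 reads in replicate 1 and 46 of 72 in replicate 2. The member of that pool with the most reads was 9 bases long, so this difference is uncertain. In Pnisr, Coq3 and Maged2, reads at the same place were assigned to different genes in the 2 libraries, so their differences are uncertain. A single-exon model at 4:21910419-21910764 had 57 reads assigned to Pnisr in replicate 2, and one at 4:21910419-21910761 had 27 reads assigned to Coq3 in replicate 1. The Maged2 chain with 27 reads in replicate 1 was the one assigned to Gm8424 in replicate 2. Of 32187 intron chains seen in both libraries, 286 were assigned to another gene in the other library, 57 of them between annotated genes. In the ribosomal Rpl39, Rpl39-201 held 80.3% and 40.6%. In the panel, 11 genes passed over all genes tested and 12 when adjusted over the list alone. Rtn4, reticulon 4, had the largest difference in the panel, with 70.4% and 33.6% on Rtn4-201 and 22.4% and 63.9% on an incomplete splice match, followed by Trdn with 49.3% and 14.5% on a 10-exon model (adjusted p 1.59e-56 by Fisher's exact test). Des-201 held 94.8% and 77.4% (adjusted p 1.66e-136 by Fisher's exact test) and an incomplete splice match 2.71% and 20.4%, and Lmna-203 of lamin A/C held 48.5% and 32.7%. With incomplete splice matches left out, 101 genes differed, of which 43 were among the 83. When annotated transcripts alone were counted, 10 genes differed.

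Exon by exon, 1516 internal exons of the 65 genes had at least 20 informative reads in each library, and 170 of them were alternative, with a pooled inclusion between 5% and 95%. M21 held 100 of these, in 38 genes, and 92 of the 100 were coding, of which 75 keep the reading frame. Of the 70 outside M21, 53 lay in Atp2a1 and 64 overlapped an annotated exon. Inclusion differed in 7 of the 100 annotated exons by Fisher's exact test, in Tnnt3, Mybpc1, Myom1, Neb and Ktn1. The mutually exclusive 41-base exons of Tnnt3 differed in opposite directions: that at 7:142513665-142513705 went into 17.7% (15.9 to 19.7) of reads in replicate 1 and 35.8% (33.6 to 38.0) in replicate 2, and that at 7:142514326-142514366 into 82.0% and 63.8%. Mybpc1, the slow-type protein C, included a 42-base exon in 72.2% and 86.1% of reads (adjusted p 1.92e-40 by Fisher's exact test), and a 59-base exon in 31.7% and 24.7%. The 294-base exon of Myom1 was included in 2.56% and 10.3%. A 93-base exon of Neb, nebulin, was included in 21.7% and 38.9%, and a 116-base exon of Ktn1 in 21.6% and 34.2%. With the limits of 5% and 95% set on the mean of both libraries in place of the pooled reads, 11 of 103 annotated exons differed. These were the same 7, a 28-base exon of Myl1 (23.6% and 21.8%) and 3 of Tpm3, of which replicate 2 held most reads. The Tpm3 exon at 3:90088401-90088476 went into 29 of 264 reads in replicate 1 and 26 of 1598, or 1.63%, in replicate 2 (adjusted p 2.07e-10 by Fisher's exact test), that at 3:90089048-90089123 into 89.0% and 98.4%, and that at 3:90091013-90091091 into 87.0% and 98.1%. With no limits, 12 of 1151 annotated exons differed, 5 of them among the 7, while those of Neb (adjusted p 0.159) and Ktn1 (0.262) did not pass Fisher's exact test. These other limits were chosen after the data were seen. With annotated transcripts alone 1 of 27 exons differed, that of Myom1. Without genomic, antisense, intergenic and incomplete splice match models 7 of 105 differed, 6 of them among the 7; the Neb exon did not pass Fisher's exact test (adjusted p 0.0922) and a 33-base exon of Trdn did (78.2% and 95.6%, adjusted p 6.45e-07). Over the 100 exons the median difference was 4.82 points. The exons of Pkm, Bin1, Camk2b and Ttn given here were chosen after their values were seen, and none of them differed. The 72-base exon of Bin1, at 18:32431671-32431742, was included in 35.9% and 34.5%. Exon 19 of Camk2b-202, 129 bases long, was included in 76.0% and 83.5%, and a 303-base exon of Ttn in 75.8% and 75.3%.

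**Figure D5:**
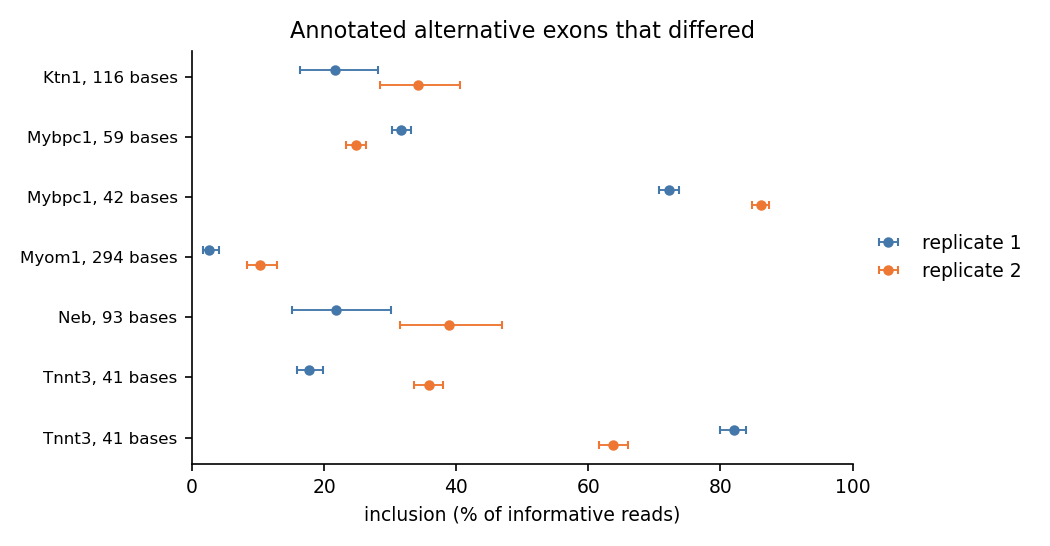
Inclusion (% of informative reads) of the 7 annotated alternative exons that differed between the libraries with limits on the pooled inclusion, with 95% Wilson intervals. The paired 41-base exons of Tnnt3 stand at 17.7% and 35.8% and at 82.0% and 63.8%.

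Outside annotated genes, 15873 loci had reads, 3729 in both libraries and 441 with at least 5 reads in each. The most abundant lay at 17:39843013-39848035 on the minus strand, with 1263 and 5407 reads. It overlaps the ribosomal RNA gene CT010467.1 on the same strand and lies opposite Gm26917 and Gm42418. The next lay at 9:77656522-77660127, antisense to Klhl31, a muscle gene of the kelch family, with 1449 and 3984 reads against 106 and 103 reads of Klhl31 itself. One antisense to Pitpnc1, a lipid transfer gene, at 11:107207892-107211763 had 212 and 336. Another, at 7:28187294-28188672, was given as intergenic in the files but overlaps Dyrk1b on the other strand, and had 185 and 270. These 4 loci were higher in replicate 2 in counts per library total, by 1.45- to 4.25-fold. The origin of reads at antisense loci was not tested, so these loci are uncertain. Spike-in transcripts, RNAs of known sequence added to the sample, took 3.64% and 1.49% of reads (2.56% ± 1.52, SD, n = 2), 2.45-fold more in replicate 1. All were of the ERCC set; of the SIRV set that the labels also name, no reads were listed. Of the spike-in reads, 408 and 149 were assigned to the antisense strand, all on 5 spike-ins with no sense read. The 57 spike-ins with sense reads, 48690 in replicate 1 and 20086 in replicate 2, had 0 antisense reads.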

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

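The tests of more slow muscle, of a lower share of muscle and of the Atp2a1 reading frame were chosen after the results were seen. The other tests in this part were made for patterns already seen in these data.

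An unannotated locus at Y:67834526-67839306 carried 145 reads in replicate 1 and 205 in replicate 2, although the labels give both animals as female. It lies outside the annotated genes that the comparisons use, and both counts exceed the 3 counts that a count of 0 allows. The nearest annotated gene, the pseudogene Gm29639, lies 5035 bases away. Annotated genes of chromosome Y had 17 and 16 reads, of which 17 and 15 were of the pseudogene Gapdh-ps15. The origin of these reads was not tested, because the genome sequence was not used here.

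The slow fibre genes were higher in replicate 2, with a median log2 ratio of 2.28. Removing the trend with transcript length left 2.40 (random lists -0.12 to 0.26), and removing that with GC content left 2.29 (-0.15 to 0.26), so the tables argue against either bias as the whole cause. More slow muscle in the piece of replicate 2 stays open: a second list of 16 slow muscle genes had a median of -0.018 (-0.23 to 0.27; -0.14 with genes at 0 at the floor), with 2 higher and 3 lower of 12 tested, the same when adjusted over the list alone. Its most abundant genes went both ways, Fabp3 with 876 and 2113 reads, Hspb6 with 1328 and 1002 and Csrp3 with 481 and 150, so its median decides nothing although it lay on the side set for a negative outcome; how that outcome was read was changed after the value was seen, and 7 of the 16 also stand in other lists. The design has 1 group, so no other biological explanation was tested.

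The adipocyte and Schwann cell markers were lower in replicate 2, with a median log2 ratio of -2.79 over both lists. Removing the trend with transcript length left -2.75 (-0.28 to 0.23). A lower share of muscle in replicate 1 would lower every other cell type in replicate 2, and the median over 5 other cell type lists was -0.088. Endothelial (-0.34), smooth muscle (-0.33), fibroblast (-0.09) and leukocyte markers (-0.07) had negative medians. Of 9 smooth muscle markers tested, 5 were lower and 0 higher in replicate 2, so its median does not describe all its members. Tendon stood at 0.59 (-0.40 to 0.42), but within its random range with a pseudocount of 10 CPM. No other list fell near -2.79, which argues against a lower share of muscle as the whole cause, while a part in it stays open. Fat and nerve carried along with the muscle of replicate 1 is a candidate source: a second list of 24 such genes, 22 with a read and 0 in the other lists, had a median of -0.74 (-0.35 to 0.35; -0.79 with genes at 0 at the floor). Of 14 tested, 6 were lower and 0 higher (8 lower when adjusted over the list alone), but its most abundant genes Dgat2 (260 and 290 reads) and Retsat (124 and 104) were not called, and how many of the list muscle fibres also express was not tested. Beyond these, no biological explanation was tested.

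The main Atp2a1 transcript lacked the coding exon of 18 bases and gained 26 bases at the splice site, in both animals. A coding transcript with another splice site is argued against, since the change of 8 bases is no multiple of 3 and leaves a remainder of 2. Loss of very short exons when reads were aligned or corrected may account for it: of 30 other coding exons of 20 bases or less that every coding transcript holds, the median inclusion was 0% (bootstrap 0 to 1.39), with 22 under 5% and 7 over 95%, against 100% over 1983 exons of 41 to 60 bases. Among the 5 exons of 16 to 18 bases, however, 2 were under 5% and 2 over 95% (median 93.2%), and the 10 of 19 to 20 bases split 5 and 5. No other biological explanation was tested.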

How the results depend on the processing

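The settings with spliced models alone, M21 exons alone, exon limits on the mean of both libraries or none, without Atp2a1 and with class in the matching key were chosen after the results were seen. No paired analysis was possible because the 2 animals form 1 group.

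Counting annotated transcripts alone reversed the log2 ratios of Aldoa (0.31), Tnni2 (0.059) and Topbp1 (-0.41), and spliced models alone reversed Topbp1 (-0.23), by leaving out unannotated models, which held most reads of Aldoa and Tnni2 and most of those of Topbp1 in replicate 2. Over 151 named genes, 9 settings gave 1314 values. Of these, 1209 kept their side of the threshold and 94 lost their call, 67 of them at a dispersion of 0.01. A further 7 gained a call and 4 reversed. Direction was not compared where a gene was uncalled at both the main and the other setting. No scaling reversed a named gene that was called at the main setting. At a dispersion of 0.01 edgeR called 173 genes, which follows from the spread it assumes. Of the 25 lists, 10 stood apart with a pseudocount of 0.1, 11 with 10, 14 with annotated transcripts alone and, of 24, 12 with at least 10 reads summed. For other single values, 205 moved by more than their spread.

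With annotated transcripts alone, Myh4 had 21.7%, Myh1 54.1% and Myh7 13.3%, the fast share was 100% for Tnnt3/Tnnt1, 0% for Atp2a1/Atp2a2, 82.0% for Mybpc2/Mybpc1 and 74.9% for Actn3/Actn2, mitochondrial genes held 0.322%, the panel median was 93.8%, 27 exons were alternative, of which 1 differed between the libraries in place of 7, and 10 dominant shares differed. With incomplete splice matches added to these, Myh4 had 40.2%, Myh1 39.2% and Myh2 11.9%. Leaving out incomplete splice matches gave a panel median of 66.1%. The 100% of Tnnt3/Tnnt1 and the 0% of Atp2a1/Atp2a2 follow from the choice itself, since no read of Tnnt1 or Atp2a1 lay on an annotated transcript.

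With 2 reads required in each library, annotated transcripts held 69.5% of reads, incomplete matches 6.85%, new combinations 4.38%, antisense 0.0151% and intergenic 0.00927%; of models, 47.1% were annotated and 7.47% had an unannotated site, and the panel median was 65.0%. The antisense and intergenic values are low by construction, since single-exon models outside genes carry names of their own library and 0 of them were joined; these held 96.3% and 97.9% of antisense reads. With 5 reads in each, the model shares were 60.8% and 4.77%. Among multi-exon transcripts, annotated held 67.1%, new combinations 5.71%, unannotated sites 19.2%, genomic 0.0525%, antisense 0.0581% and intergenic 0.0297%. Without spike-ins and mitochondrial genes, unannotated sites held 17.8%. Without Atp2a1, annotated held 75.9%, incomplete matches 8.91%, new combinations 5.92% and unannotated sites 3.73%. The key with class gave 126 differing dominant shares, and M21 exons alone 100 alternative exons. With exon limits on the mean of both libraries 11 annotated exons differed, and 12 with none.

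The correlation was 0.832 with a pseudocount of 0.1, 0.973 with 10, 0.933 at 10 reads or more, 0.920 by Spearman and 0.800 over transcripts. A minimum of 10 reads left 6864 genes in both libraries, and 50 reads summed left 591 unannotated dominant transcripts, by construction. Apart from the minimums and settings whose construction is named, the cause was not tested.

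Leaving out each library gave 13792 to 13844 genes and, by class, 63.5% to 66.1% annotated, 7.63% to 8.43% incomplete, 4.97% to 5.31% new combinations, 17.1% to 17.5% unannotated sites, 1.96% to 2.69% genomic, 1.18% to 2.93% antisense and 0.221% to 0.413% intergenic. Models were 18.1% to 19.9% annotated and 19.98% to 20.96% with an unannotated site. Myh4 ranged from 48.3% to 52.0%, Myh1 from 29.999% to 34.9%, Myh2 from 8.48% to 11.2% and Myh7 from 1.73% to 13.1%. The fast shares ranged from 87.8% to 98.3% (Tnni2/Tnni1), 44.0% to 84.5% (Tnnt3/Tnnt1), 95.0% to 99.1% (Tnnc2/Tnnc1), 96.2% to 98.6% (Mylpf/Myl2), 99.4% to 99.9% (Atp2a1/Atp2a2), 97.0% to 98.7% (Casq1/Casq2), 88.4% to 91.0% (Myoz1/Myoz2), 59.9% to 62.9% (Mybpc2/Mybpc1) and 69.4% to 72.9% (Actn3/Actn2). The panel median was 53.7% to 58.0%, alternative exons 165 to 179, unannotated dominant transcripts 663 to 773 since fewer genes reach the minimum, mitochondrial reads 0.176% to 0.247% and spike-in reads 1.49% to 3.64%. Leaving out a library gave no value for the correlation, the gene, dominant share and exon tests and the list tests, which compare both. Depth limits the gene test below 100 reads, where simulated 2-fold changes were often missed.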

Other observations

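No test was run for the values in this part, and none was chosen after a result was seen. The labels give both libraries the same donor identifier, although the animal numbers differ, and this was not resolved from the sources used here. Of the ERCC spike-ins, 60 were seen in replicate 1 and 48 in replicate 2, with 46 in both. Counting sense reads alone, these numbers were 55, 44 and 42, since 5 spike-ins had antisense reads only. Among the 10 with at least 100 sense reads in each library, replicate 1 held 1.65 to 3.36 times as much as replicate 2 in counts per library total. The mean model length per read was 2468 bases in replicate 1 and 2520 in replicate 2. Other unannotated loci of chromosome Y had 37 and 51 reads and 13 and 20 reads.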
